A study of Mus musculus with 30 samples.

How the data were processed

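Spleen cells of Smc3-WT and Smc3-cKO mice, depleted of red blood cells, were profiled with the Chromium Single Cell 3′ Reagent Kit, and 2 libraries per genotype were available. The series lists 30 samples. The other 26, bulk RNA-seq of sorted cDC, pDC and pre-DC, ChIP-seq of PU.1 and H3K27Ac with inputs, and Hi-C, came without processed data and were not analysed here. Per the file headers, the deposited values are UMI counts per gene and barcode made with Cell Ranger 7.0.0. Per the submitters' processing notes, the genome build was mm10, and deepTools and Juicer were used, for which data is not stated. The counts were whole numbers for 32285 genes in every library, with no scaling. The lowest total per barcode was 500 or 501 UMIs, so barcodes below that had been removed before deposit, and any further filter is not stated. Depth was 40367056 to 51299056 UMIs per library, over 9074 to 16096 barcodes, and the median percentage of mitochondrial UMIs was 7.51 and 3.25 in the Smc3-WT libraries and 5.64 and 3.97 in the Smc3-cKO libraries. Xist was detected at 1315 and 1673 CPM against 1175 and 1772 CPM in all cDC-like cells, so all 4 libraries carry RNA of female cells.

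Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, 46886 of 53644. Doublets were called in each library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes, and removed. The caller marked 0.859% and 6.21% of the Smc3-WT cells and 3.61% and 6.37% of the Smc3-cKO cells, against expected rates of 12.9%, 11.5%, 7.26% and 11.3%, so doublets remain, most of all in Smc3-WT replicate 1. Kept were 44793 cells. Their counts were scaled to 10000 per cell and log-transformed after adding 1. Clustering used 2000 variable genes chosen with the library as batch, 30 principal components, no integration, 15 nearest neighbours and Leiden resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). Immunoglobulin and T cell receptor segments, mitochondrial, ribosomal protein and haemoglobin genes were left out of the variable genes. The first level gave 29 clusters. The 4290 cells of the myeloid ones were clustered again with 20 components, which gave 24 clusters in their place and 48 in all.

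Clusters were named from fixed marker lists. A marker counted where it reached 20 CPM in the cluster and a log2 ratio of at least 1 over clusters of other names, after adding 5 CPM to both. A name needed at least 3 such markers, a share of at least 0.5 of the class's markers, and leading genes (the 10 largest ratios at 50 CPM or more) that did not go against it. Clusters were also left unnamed where B or T cell markers of a second lineage reached a share of 0.25 of their level in B or T clusters in clusters with at least the median UMIs, or 0.5 for both together in any cluster. This scoring rule was set after seeing the data, the lists were not. Of the clusters, 37 were named and 11 were left unnamed, 10 because they carried markers of 2 lineages and 1 because too few markers were detected. Unnamed cells made up 10.1% and 4.67% of the Smc3-WT libraries and 5.7% and 1.58% of the Smc3-cKO libraries. The names rest on RNA alone and can differ from sorted populations. A class was tested if each library held at least 20 of its cells, which left 13 of 18 classes. The sum of all cDC-like cells was tested as well.

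Raw counts were summed per library and class and compared between genotypes, 2 libraries against 2, with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg within each class at a threshold of 0.05. All log2 changes are Smc3-cKO over Smc3-WT, with a standard error from the same fit. CPM of single genes are TMM-scaled, and CPM summed over gene lists or shown for Plcb4 by class are not. The difference in the genotype effect between 2 cell types was tested as an interaction with the library as a block. Shares of classes were tested with edgeR on cell numbers, without TMM and with all kept cells of a library as its size. Intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error only. Chosen before the data were examined were the comparisons and their tests, the filters on cells, the marker lists, the 36 gene lists, the rule for naming genes and all alternatives but 3. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Single members were also adjusted over the list alone. Listed symbols that the annotation lacks (Ahsp, Amica1, Clec7a, Marchf1, Mx1, Mx2) were passed over.

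Genes were named by a fixed rule. In each DC class they were the 12 with the largest fold in each direction, among genes past the threshold, with both libraries of a genotype on the same side of both of the other and a mean of at least 50 CPM in the higher genotype. In other classes they were the 4 largest in each direction, and from each list up to 4 members with the smallest adjusted p. Smc3 with the cohesin list and a set of DC factors were named whatever their p. Receptor segments, haemoglobin, sex-linked and unnamed genes were passed over by the rule, and the text describes only some of the genes that it takes. Members of the interaction results, the genes at the loci of Plcb4 and Itgad, Itgam and 9630028H03Rik were chosen for mention after their values were seen. A gene with 0 counts in a genotype is given a lower bound of its fold against a floor of 3 counts over that genotype.

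The tests were tested on simulated data, negative binomial counts with the levels, depths and spread of each class in which 200 genes were changed. In the cDC1, cDC2, all cDC and pDC sums edgeR recovered 16.7%, 19.7%, 9.2% and 19.4% of 2-fold changes, 79.3%, 92.4%, 68.9% and 84.1% of 4-fold changes and 96.6%, 95%, 100% and 100% of 8-fold changes. It made 4, 11, 8 and 2 false calls. Interaction tests recovered 73.8% (cDC1 against cDC2) and 83.3% (all cDC against pDC) of 8-fold differences. On simulated lists, camera with an estimated correlation recovered 0 in every class tried. Fry recovered the changed list in the cDC2 and classical monocyte sums and not in the cDC1, all cDC, pDC and B cell sums. The simulated genes were drawn independently of each other, so these lists carry no correlation between genes. For shares, an 8-fold change was recovered at a simulated dispersion of 0.05 and not at 0.5.

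The alternatives tried were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, each library left out in turn, 1 fit over all classes, equal numbers of cells per library, stricter cell filters (at most 5% mitochondrial UMIs and at least 500 genes), doublets kept, Leiden resolution 2, clustering without the called genes, and for shares also TMM and a denominator without lymphoid and erythroid cells. At most 20% mitochondrial UMIs, doublets by rank of their score and keeping the clusters with 2 lineages were added after seeing the data. Random steps used seed 1. Other software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are those of the RefSeq annotation of GRCm38.p6. Left out were a correction for free RNA, because empty droplets are not in the deposited counts, and any integration across libraries, which could remove differences between genotypes.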

Results

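Spleen cells depleted of red blood cells were profiled by droplet single-cell RNA sequencing in 4 libraries, 2 from Smc3-WT mice and 2 from Smc3-cKO mice. Smc3 encodes a subunit of cohesin, the ring-shaped complex that forms chromatin loops, and the series asks how cohesin and PU.1, the myeloid transcription factor encoded by Spi1, act in conventional dendritic cells (cDC). The bulk RNA-seq of sorted cDC, plasmacytoid DC (pDC) and bone marrow DC precursors, the ChIP-seq and the Hi-C that the labels list, 26 samples in all, were not analysed here. Smc3-WT replicates 1 and 2 held 51299056 and 48970568 UMIs in 16096 and 14352 barcodes, and Smc3-cKO replicates 1 and 2 held 40367056 and 46678046 UMIs in 9074 and 14122 barcodes. After filtering, 12121, 13081, 6881 and 12710 cells remained in the same order. Median depth was higher in Smc3-cKO replicate 1, with 3844.5 UMIs per barcode against 2728, 2806 and 2772 in the other libraries. The labels do not say whether the libraries of a genotype came from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

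Clusters were assigned to 18 classes by fixed markers, and 13 classes held at least 20 cells in every library and were tested. The cDC1-like class, named by genes such as Xcr1 and Clec9a of the cross-presenting subset, held 78 and 80 cells in the Smc3-WT libraries and 69 and 30 in the Smc3-cKO libraries. The cDC2-like class, named by Sirpa, Clec4a4 and Cd209a among others, held 90 and 162 against 62 and 156 cells. The pDC-like class, named by Siglech and Ccr9 among others, held 38 and 77 against 93 and 47 cells. Mature cDC-like cells, which carry Ccr7 and Fscn1, numbered 76 and 36 against 27 and 17, too few in Smc3-cKO replicate 2 for a test of their own, and enter the sum of all cDC-like cells.

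Smc3 RNA, the targeted transcript (chromosome 19, 53600396 to 53645831 in the RefSeq annotation of GRCm38.p6), was not lower in Smc3-cKO DC. In cDC1-like cells its mean was 110 CPM in Smc3-WT and 180 CPM in Smc3-cKO, a log2 change of 0.68 (SE 0.36). In cDC2-like cells the log2 change was 0.02 (SE 0.29) and in pDC-like cells -0.01 (SE 0.35). The lowest value over the classes was -0.55 (SE 0.35) in neutrophil-like cells. Smc3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in 0 of 14 tests, 0 had an unadjusted p under 0.05, and DESeq2 called it in 0. The kit targets the 3′ end of transcripts, so the counted tags may lie outside the deleted part. The labels name neither that part nor the Cre line, so Smc3 RNA checks nothing about the genotype labels here. The other cohesin subunits and regulators did not pass the test in any DC class: of 12 listed genes, Rad21 changed by 0.29 (SE 0.27), Stag2 by 0.16 (SE 0.26), Nipbl by -0.04 (SE 0.29) and Ctcf by 0.00 (SE 0.23) on the log2 scale in all cDC-like cells, and 0 passed when adjusted over the list alone.

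No DC transcription factor gene passed the test over all genes in any DC class. In all cDC-like cells, Spi1 had a log2 change of -0.01 (SE 0.29, means of 373 and 370 CPM), Irf8, required for cDC1, 0.19 (SE 0.34), Irf4, a cDC2 factor, 0.10 (SE 0.43), Batf3, a cDC1 factor, -0.49 (SE 0.26) and Zbtb46, the pan-cDC factor, -0.71 (SE 0.33). Of the 22 DC transcription factor genes tested there, Tcf4, which drives pDC development, was the 1 that passed when adjusted over the list alone, with a log2 change of 1.92 (SE 0.40). These are RNA levels, and PU.1 protein and its binding were not measured in these libraries.

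The first comparison asked whether the frequency of splenic cell classes differed between genotypes. Both monocyte classes were a larger part of all cells kept in each Smc3-cKO library than in either Smc3-WT library, without passing the test: classical monocyte-like cells, which carry Ly6c2 and Ccr2, were 0.454% and 1.11% of cells in Smc3-WT and 2.12% and 2.60% in Smc3-cKO, and nonclassical monocyte-like cells, which carry Ace and Treml4, were 0.784% and 0.917% against 4.17% and 1.45%. Of the named cells that are neither B, T, NK nor erythroid, classical monocyte-like cells were 5.56% and 17.4% in Smc3-WT and 14.5% and 33.0% in Smc3-cKO, which overlap (log2 change 1.05, adjusted p 0.574), and nonclassical ones 9.61% and 14.4% against 28.6% and 18.4% (log2 change 0.97, adjusted p 0.574). CD4 T-like cells were a smaller part of all cells kept in each Smc3-cKO library, at 11.6% and 11.7% in Smc3-WT and 8.33% and 10.9% in Smc3-cKO. All cDC-like cells together were 2.07% ± 0.0849 (SD, n = 2) of Smc3-WT cells and 1.95% ± 0.495 (SD, n = 2) of Smc3-cKO cells. The cDC1-like share was 0.628% ± 0.0226 against 0.618% ± 0.540, the cDC2-like share 0.992% ± 0.351 against 1.07% ± 0.233 and the pDC-like share 0.452% ± 0.194 against 0.860% ± 0.693 (SD, n = 2 for each). No class passed edgeR's quasi-likelihood test on cell numbers with Benjamini-Hochberg adjustment, and 1 class, megakaryocyte or platelet-like cells, had an unadjusted p under 0.05. Classical monocytes had a log2 change of 1.59 with an adjusted p of 0.671, nonclassical monocytes 1.72 with 0.671, and all cDC -0.09 with 0.96. The classical monocyte value was 2.38 without Smc3-WT replicate 2, and the nonclassical one 0.77 without Smc3-cKO replicate 1 and 2.29 without Smc3-cKO replicate 2. The exact two-sided permutation test of 2 against 2 libraries cannot go below 0.333. Red cell content differed between libraries in both genotypes, with erythroid-like cells at 7.32% and 0.910% in Smc3-WT and 5.89% and 0.102% in Smc3-cKO.

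**Figure D1:**
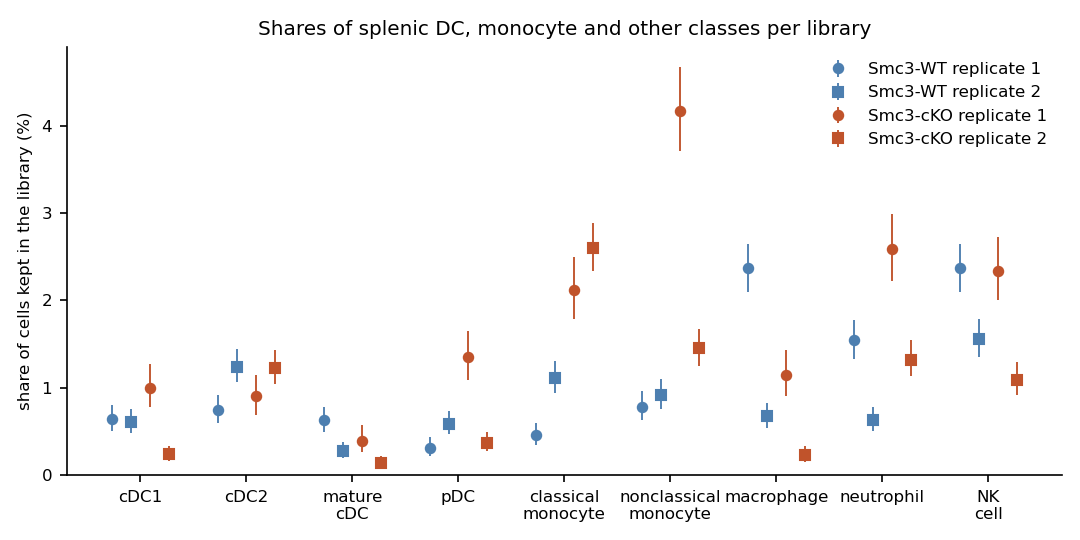
Share of cells kept in each library (%, linear axis) for 9 classes, with 1 point per library and bars for the 95% Clopper-Pearson interval, which covers counting error only. The classical monocyte shares of the Smc3-cKO libraries, 2.12% and 2.60%, lie above those of the Smc3-WT libraries, 0.454% and 1.11%.

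In cDC1-like cells a small set of genes changed by a large factor. Frmd5, a FERM-domain protein gene (chromosome 2, 121545529 to 121807087 in GRCm38.p6), fell from 253 to 6.35 CPM, a log2 change of -5.12 (SE 0.49, adjusted p 0.00102). Adam23 and Adam22, cell-surface members of the ADAM family that lack protease activity, also fell, with log2 changes of -2.98 (SE 0.38) and -3.24 (SE 0.44), as did P3h2, a collagen prolyl hydroxylase, with -3.20 (SE 0.42), and Apol7c, an apolipoprotein L family gene found in mature DC, with -3.61 (SE 0.47). Pcsk5, a proprotein convertase, had 0 counts in both Smc3-cKO libraries and was at least 14.3-fold lower, against a floor of 3 counts over the genotype. Gria3, a glutamate receptor subunit, was the only gene that rose, from 16.5 to 141 CPM (log2 change 3.08, SE 0.44, adjusted p 0.0118). Median depth in this class was 3368.5 and 6494.5 UMIs in Smc3-WT and 2074 and 8315.5 UMIs in Smc3-cKO. At Leiden resolution 2, cDC1-like cells fell into a cluster led by Xcr1, Cxcl9 and Apol7c (median 1189 UMIs) and 1 led by Xcr1 and Clec9a (8757.5 UMIs). Whether the mix of these cells contributes to the changes, such as that of Apol7c, was not tested.

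No cDC1 identity gene passed the test in cDC1-like cells. Of 17 members 0 passed, also when adjusted over the list alone, with log2 changes of -1.35 (SE 0.49) for the adhesion molecule Cadm1, -1.01 (SE 0.43) for the RNA sensor Tlr3 and 0.54 (SE 0.32) for Ifi205. In the DC maturation list, 1 of 11 genes fell (Apol7c) and 2 fell when adjusted over the list alone, with Serpinb6b at -1.60 (SE 0.48). This list passed camera as lower (adjusted p 2.28e-06), and adjusted p = 0.82 with an estimated correlation. The B cell genes gave a larger camera result in the same cells (median log2 change -1.08, adjusted p 4.03e-17; adjusted p = 0.82 with an estimated correlation), their summed level was 3340 and 2310 CPM in Smc3-WT against 2400 and 596 CPM in Smc3-cKO, and 0 of 15 passed over all genes while 2 passed when adjusted over the list alone. Of 6721 genes tested in cDC1-like cells, 1 rose and 6 fell by edgeR's quasi-likelihood test, and Apol7c belongs to a multigene family whose members may share reads. With equal numbers of cells 1 of the 6 still tested kept its call. With the stricter cell filters 4 of 7 did, and at Leiden resolution 2 it was 4 of 6 still tested. The 7 genes kept their calls when each library was left out in turn, with total counts of 31 without Smc3-WT replicate 1, 127 without Smc3-WT replicate 2, 79 without Smc3-cKO replicate 1 and 56 without Smc3-cKO replicate 2, and DESeq2 called 15 genes, these 7 among them.

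In cDC2-like cells the genes that fell included abundant transcripts of the class. Dscam, an immunoglobulin-superfamily adhesion molecule (chromosome 16, 96587452 to 97171113), went from 1700 to 77.3 CPM, a log2 change of -4.43 (SE 0.47, adjusted p 0.00225), Adam23 (chromosome 1, 63445717 to 63596111) from 2000 to 232 CPM (log2 change -3.12, SE 0.45) and Frmd5 from 1020 to 80.7 CPM (log2 change -3.62, SE 0.45). Esrrg, an orphan nuclear receptor, and Tmem132c had 0 counts in both Smc3-cKO libraries and were at least 42.2-fold lower. Ffar2, a short-chain fatty acid receptor, fell with a log2 change of -2.90 (SE 0.31), Asb2, a ubiquitin ligase subunit, with -2.40 (SE 0.28), and Adgre1, which encodes the F4/80 macrophage antigen, with -2.36 (SE 0.29). Cd4, a surface marker of 1 splenic cDC2 subset, fell from 116 to 17.1 CPM, a log2 change of -2.60 (SE 0.41, adjusted p 0.0184). The Ras exchange factor Rasgrp3, the efflux pump Abcb1a, the tetraspanin Tspan9 and the transglutaminase Tgm2 fell with log2 changes of -3.11, -3.02, -3.04 and -3.05, and Ccdc192 and Adam22 with -3.60 and -3.09.

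Fewer genes rose in the same cells. Plcb4, a phospholipase C subunit, rose from 39.8 to 358 CPM (log2 change 3.23, SE 0.36, adjusted p 0.00225), and Plcb1 from 17.6 to 200 CPM (log2 change 3.24, SE 0.63). Siglech, the sialic acid-binding receptor of pDC, rose from 45.7 to 196 CPM (log2 change 2.10, SE 0.33, adjusted p 0.0184), and Xdh, xanthine dehydrogenase, from 24.5 to 119 CPM. Gria3 rose with a log2 change of 1.91, Slc41a2, a magnesium transporter, with 2.06, Pdzd4 with 1.81 and the cytokine receptor gene Lifr with 1.57. Klra17 also passed, with a log2 change of 1.95, and belongs to a family of near-identical receptor genes that counting may split. Cells closest to cDC2 but left out of the class were mostly from Smc3-WT, 53 and 124 against 11 and 16 in Smc3-cKO. With them included, 6 genes rose instead of 10. When cells were clustered without the called genes, such a cluster had Siglech and Cd209a among its leading genes, beside Adam23 and Dscam. Leaving such cells out may thus lower the Smc3-WT level of Siglech.

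**Figure D2:**
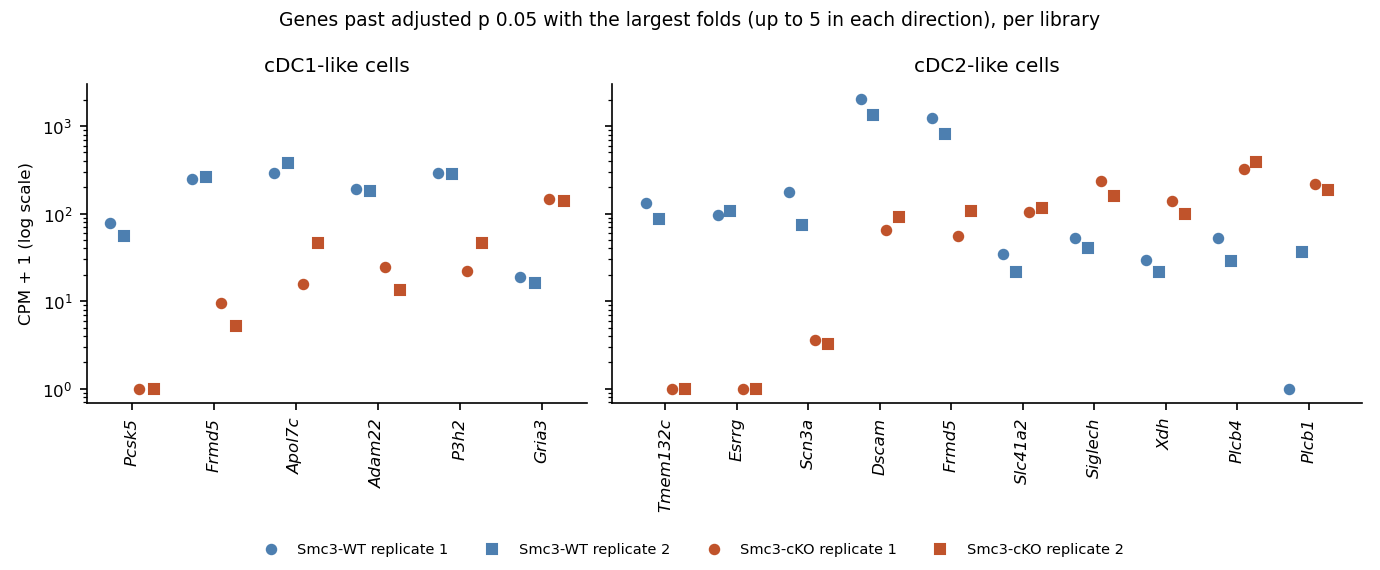
CPM + 1 of each library (log axis) for the genes past an adjusted p of 0.05 with the largest folds, up to 5 in each direction, in cDC1-like and cDC2-like cells, 1 point per library. In every gene drawn, both Smc3-cKO libraries lie on the same side of both Smc3-WT libraries, as for Dscam in cDC2-like cells with means of 1700 and 77.3 CPM.

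The fixed gene lists moved in both directions in cDC2-like cells. Of 13 pDC identity genes tested, Siglech rose and 7 rose when adjusted over the list alone, with log2 changes of 1.70 (SE 0.43) for Tcf4, 1.35 (SE 0.35) for the chemokine receptor Ccr9 and 1.51 (SE 0.45) for Bst2. Their summed level was 3870 and 4110 CPM in Smc3-WT and 8420 and 8110 CPM in Smc3-cKO, and camera gave an adjusted p of 3.22e-09 (adjusted p = 0.481 with an estimated correlation). How much of this rise comes from the shift between cDC2 clusters described below was not tested for the list. Nor was the effect of the cells closest to cDC2 that were left out of the class, most of them from Smc3-WT. Of 5 Notch-dependent splenic cDC2 genes tested, Cd4 fell and 3 fell when adjusted over the list alone, with Dtx1, a Notch target, at -2.65 (SE 0.55) and Clec4a4 at -2.16 (SE 0.45), while Notch2 itself was at 0.14 (SE 0.32). That list gave a camera adjusted p of 2.53e-06 (adjusted p = 0.481 with an estimated correlation).

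Among genes shared by all cDC, Ffar2 and Asb2 fell of 15 tested, 3 fell and 1 rose when adjusted over the list alone, and the costimulatory gene Cd86 was at -1.10 (SE 0.30). This list passed camera (adjusted p 0.000258, and 0.481 with an estimated correlation) and was the only DC list that passed fry (adjusted p 0.00806). In simulation, fry recovered the changed list in the cDC2 sums and in no other DC sums. Of 9 pattern recognition receptor genes, Nod1, a sensor of bacterial peptidoglycan, fell (log2 change -1.77, SE 0.33) and 4 fell when adjusted over the list alone, with Tlr1 at -1.78 (SE 0.38) and Tlr7 at -1.24 (SE 0.40); camera gave an adjusted p of 0.0018 (adjusted p = 0.497 with an estimated correlation). Of 15 cDC2 identity genes 0 passed over all genes, and adjusted over the list alone 2 rose and 1 fell, with Cd209a at 1.95 (SE 0.40), Clec10a at 2.23 (SE 0.50) and Clec4a4 at -2.16 (SE 0.45). Cd209a has close homologues in its gene cluster, so its counts are uncertain. Of 11 B cell genes Bank1 fell (log2 change -1.92, SE 0.35) and 5 fell when adjusted over the list alone, and the list summed to 1490 and 771 CPM in Smc3-WT and 618 and 528 CPM in Smc3-cKO (camera adjusted p 1.44e-06; adjusted p = 0.58 with an estimated correlation).

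Different clusters held most of the cells named cDC2-like in the 2 genotypes. When cells were clustered without the genes called in any DC class, a cluster led by Cd209a and Cyp7b1 held 17.9% ± 5.3 (SD, n = 2) of cDC2-like cells in Smc3-WT and 61.3% ± 1.98 (SD, n = 2) in Smc3-cKO, and a cluster led by Adam23, Frmd5 and Dscam held the rest. The cells that went to the Cd209a-led cluster numbered 13 and 35 against 42 and 97. A further cluster led by Cd209a and Cyp7b1 was closest to cDC2 but left unnamed, because leading genes of other classes went against the name. It held 45 and 105 Smc3-WT cells and 5 and 8 Smc3-cKO cells, which these shares leave out. With it included the Cd209a-led share in Smc3-WT would be larger and the difference between genotypes smaller. In all, 10 genes rose and 53 fell of 7185 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, DESeq2 called 66 genes with 48 shared, and the count was 201 without Smc3-WT replicate 1, 846 without Smc3-WT replicate 2, and 107 without either Smc3-cKO library, with 60 of the 63 kept without Smc3-WT replicate 1, 62 without Smc3-WT replicate 2, 56 without Smc3-cKO replicate 1 and 50 without Smc3-cKO replicate 2. The calls of Adam23 and Pdzd4 were lost without Smc3-cKO replicate 2 (log2 change -2.93 and 1.72, adjusted p 0.124 and 0.0625), those of Nod1 and Bank1 without Smc3-cKO replicate 1 (-1.55 for both, adjusted p 0.0788 and 0.0723) and that of Tgm2 without Smc3-WT replicate 2 (-2.16, adjusted p 0.0568). A further 53 and 124 Smc3-WT cells and 11 and 16 Smc3-cKO cells lay in clusters closest to cDC2 that also carried markers of a second lineage and were kept out of the class by a threshold set after seeing the data; with them included, 33 genes passed and 28 of the 63 kept their call.

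With all cDC-like cells summed, 2 DC maturation genes passed the test, both lower in Smc3-cKO. Socs2, a feedback inhibitor of cytokine signalling, fell with a log2 change of -2.42 (SE 0.36, adjusted p 0.0452) and Serpinb6b, a serine protease inhibitor, with -2.47 (SE 0.37, adjusted p 0.0471). Of 20 maturation genes tested, these 2 fell, 12 fell when adjusted over the list alone and 0 rose, and their summed level was 4620 and 3260 CPM in Smc3-WT against 1910 and 2050 CPM in Smc3-cKO (camera adjusted p 1.51e-18; adjusted p = 0.551 with an estimated correlation). The B cell genes in the same sums went from 2620 and 2080 CPM in Smc3-WT to 1550 and 527 CPM in Smc3-cKO, with 0 of 17 past the test over all genes and 9 lower when adjusted over the list alone (camera adjusted p 2.15e-11; adjusted p = 0.551 with an estimated correlation). Mature cDC-like cells were 76 of 244 and 36 of 278 of these cells in Smc3-WT and 27 of 158 and 17 of 203 in Smc3-cKO. Their median depth was 4308.5 and 4323 UMIs in Smc3-WT and 803 and 3384 UMIs in Smc3-cKO. The sum mixes the subsets, so it does not show whether maturation genes fell within mature cDC-like cells. Siglech rose with a log2 change of 2.48 (SE 0.30), Ccr2, the receptor for monocyte emigration from marrow, with 1.79 (SE 0.26), and Plcb1 with 2.28. Nrg1, a growth factor gene, had 0 counts in both Smc3-WT libraries and was at least 46.8-fold higher.

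Genes that fell in all cDC-like cells included Dscam (log2 change -4.29, SE 0.56), P3h2 (-3.57, SE 0.39), Adam23 (-3.19, SE 0.37), Adam22 (-3.13, SE 0.27), Frmd5 (-3.03, SE 0.43), Mxd1, a Myc antagonist (-2.98, SE 0.38), and Adgre1 (-1.95, SE 0.30). Without TMM scaling, Mxd1 was at 164 and 92.2 CPM in the Smc3-WT sums, but at 16.7 and 13.8 CPM in cDC1-like and 27.6 and 33.0 CPM in cDC2-like cells. Neither of these subsets thus accounts for its level in the sum. Dkk2, a secreted Wnt inhibitor, and Pcsk5 had 0 counts in both Smc3-cKO libraries and were at least 29.5-fold and 20.7-fold lower. Of 9367 genes tested, 5 rose and 32 fell by edgeR's quasi-likelihood test. DESeq2 called 129, these 37 among them, and the count was 63 without Smc3-WT replicate 1, 253 without Smc3-WT replicate 2, 245 without Smc3-cKO replicate 1 and 125 without Smc3-cKO replicate 2, with at least 34 of the 37 kept each time. With at most 5% mitochondrial UMIs and at least 500 genes per cell, 10 passed.

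In pDC-like cells the MHC class II pathway genes were lower in Smc3-cKO as a group by camera at the preset correlation. By fry 0 lists passed in this class. Their summed level was 5530 and 6030 CPM in Smc3-WT and 3030 and 3150 CPM in Smc3-cKO. H2-Ab1 had a log2 change of -1.42 (SE 0.31), H2-Eb1 -1.47 (SE 0.32), H2-Aa -1.12 (SE 0.37) and Cd74, the invariant chain, -1.18 (SE 0.36). Of 10 members 0 passed over all genes and 4 fell when adjusted over the list alone, and camera gave an adjusted p of 1.92e-07 (adjusted p = 0.747 with an estimated correlation). B cells also express class II genes, and the B cell genes summed to 2170 and 2950 CPM in pDC-like cells of Smc3-WT and 1540 and 2030 CPM in Smc3-cKO (camera adjusted p 0.0204; adjusted p = 0.747 with an estimated correlation). In CD4 T-like cells, which lack both, the class II genes summed to 1130 and 339 CPM against 369 and 268 CPM.

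The pDC identity genes did not pass in pDC-like cells. Their summed level was 26600 and 31900 CPM in Smc3-WT and 30800 and 33300 CPM in Smc3-cKO, with 0 of 18 members past the test, also when adjusted over the list alone, and a log2 change of 0.05 (SE 0.40) for Irf8. Of 13 interferon-stimulated genes, 0 passed over all genes and Slfn5 rose when adjusted over the list alone, with a log2 change of 2.56 (SE 0.51), beside 1.19 (SE 0.40) for Ifi44 and 1.12 (SE 0.42) for Oasl2; camera gave an adjusted p of 1.19e-06 (adjusted p = 0.747 with an estimated correlation). Of 4952 genes tested in pDC-like cells, edgeR's quasi-likelihood test called 0, DESeq2 called 0, and 171 had an unadjusted p under 0.05. Without Smc3-WT replicate 1, Smc3-WT replicate 2, Smc3-cKO replicate 1 or Smc3-cKO replicate 2 the count was 10, 33, 9 or 8.

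**Figure D3:**
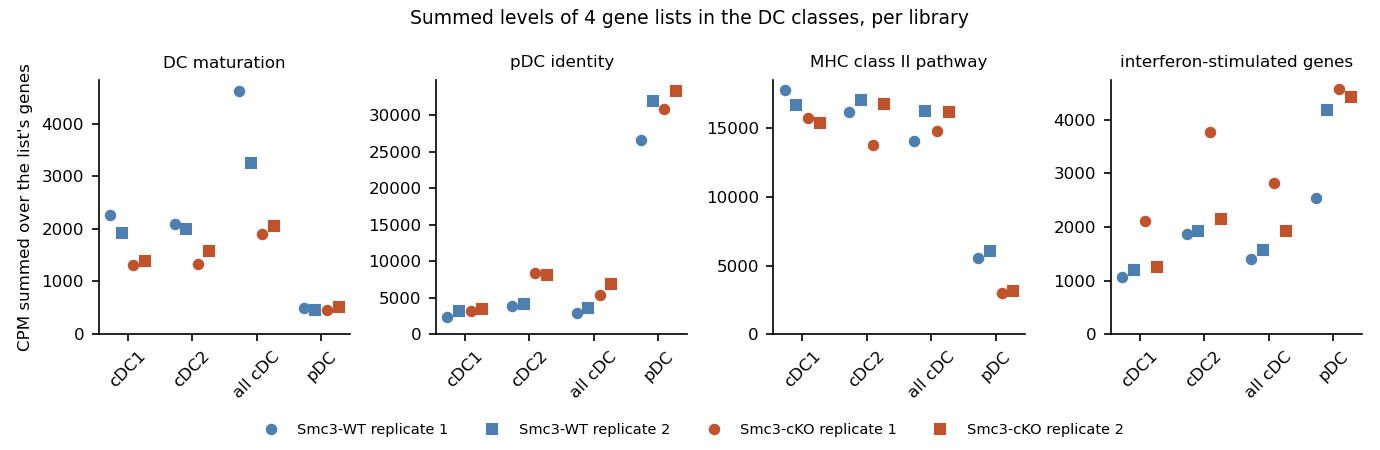
CPM summed over the genes of 4 fixed lists (linear axes) in the DC classes, with 1 point per library. The pDC identity genes in cDC2-like cells lie at 3870 and 4110 CPM in Smc3-WT and 8420 and 8110 CPM in Smc3-cKO, and the MHC class II genes in pDC-like cells at 5530 and 6030 CPM against 3030 and 3150 CPM.

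Interferon-stimulated genes also passed camera as higher in cDC1-like (adjusted p 0.0332; adjusted p = 0.82 with an estimated correlation) and cDC2-like cells (adjusted p 0.0264; adjusted p = 0.834 with an estimated correlation). There 0 of 13 and 0 of 23 members passed, also when adjusted over the list alone. The levels rested on 1 library: in cDC2-like cells the list summed to 1860 and 1930 CPM in Smc3-WT, 3780 CPM in Smc3-cKO replicate 1 and 2150 CPM in Smc3-cKO replicate 2. The median log2 change was 0.30 in cDC2-like and 0.15 in cDC1-like cells with all libraries, and -0.19 and -0.01 without Smc3-cKO replicate 1. In pDC-like cells it was 0.50 both with and without that library. Genes of nuclear-encoded oxidative phosphorylation were higher by camera in cDC1-like and cDC2-like cells (adjusted p 0.00014 and 2.58e-07; adjusted p = 0.82 and 0.775 with an estimated correlation), with 0 of 84 and 0 of 85 members past the test, also when adjusted over the list alone. Their median log2 change was 0.20 in cDC1-like and 0.44 in cDC2-like cells, -0.05 and 0.05 without Smc3-WT replicate 1, and 0.81 and 1.35 without Smc3-WT replicate 2.

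The cDC subsets were then compared with each other. Of 6205 genes tested in both, Adam22, Adam23 and Frmd5 fell in both subsets, all 3 of the genes that fell in cDC1-like cells there against 40 in cDC2-like cells, where independent lists would share 0.0193. Gria3 rose in both. The same libraries give both tests, so the overlap does not come from independent samples. Of the 40 genes that fell in cDC2-like cells, 39 had a log2 change below 0 in cDC1-like cells, with a median of -1.22. Of 2995 genes called in neither subset and below 0 in cDC2-like cells, 61.6% were below 0 in cDC1-like cells, with a median of -0.11. The test of the difference between the subsets called 11 genes by edgeR and 1 by DESeq2. Plcb4 (2.06, SE 0.35) and the calcium channel subunit gene Cacnb2 (2.36, SE 0.32) had a higher log2 change in cDC2-like than in cDC1-like cells, and Stmn1, a microtubule regulator of dividing cells (-3.05, SE 0.57), and Klri1 (-1.81, SE 0.30) a lower one. The count was 28 without Smc3-WT replicate 1, 174 without Smc3-WT replicate 2, 24 without Smc3-cKO replicate 1 and 1 without Smc3-cKO replicate 2.

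The test of the difference between conventional and plasmacytoid DC called 63 genes, 36 with a higher and 27 with a lower change in pDC-like cells. The log2 change of Siglech in pDC-like cells minus that in all cDC-like cells was -2.64 (SE 0.34, adjusted p 1.41e-07). The same difference was -3.40 (SE 0.44) for Ccr2, -2.91 (SE 0.39) for Ly6c2, a monocyte and pDC surface antigen, -1.66 (SE 0.28) for Tcf4 and -2.84 (SE 0.42) for Cd209a. For the class II genes H2-Ab1, H2-Aa and H2-Eb1 it was -1.33, -1.16 and -1.21, and for Cd74 -1.12. Cd4 had a higher change (1.86, SE 0.45) in pDC-like cells. In both cell types the edgeR test used the library as a block. The 63 include genes of other cell types whose level followed 1 library, such as the haemoglobin gene Hbb-bt, at 1180 and 19.0 CPM in Smc3-WT and 90.9 and 9.38 CPM in Smc3-cKO pDC-like cells, and the immunoglobulin gene Igha, at 11.8 and 563 against 63.8 and 5.78 CPM in all cDC-like cells. DESeq2 called 20 genes, and without Smc3-WT replicate 1 edgeR called 29.

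Among the 10 other classes, 8 calls were made by edgeR's quasi-likelihood test and most were of the same few genes. Plcb4 rose in NK-like cells from 98.4 to 842 CPM (log2 change 3.08, SE 0.29) and in nonclassical monocyte-like cells from 8.99 to 217 CPM (log2 change 4.61, SE 0.47). Plcb1 had 0 counts in Smc3-WT NK-like cells and was at least 95.3-fold higher in Smc3-cKO, and the unnamed transcript 9630028H03Rik, which lies between both genes, was at least 66.1-fold higher in NK-like and 104-fold higher in macrophage-like cells. Itgad, an integrin subunit gene that overlaps 4931431B13Rik, rose in NK-like cells from 55.2 to 466 CPM and Itgam, the integrin subunit CD11b, in macrophage-like cells from 14.2 to 332 CPM. The remaining call was Plcb1 in macrophage-like cells, at 4.49 CPM in Smc3-WT, from few counts, and 225 CPM in Smc3-cKO. B, CD4 T, CD8 T, regulatory T and innate-like T cells, neutrophils and classical monocytes had 0 calls by edgeR, with 66 (innate-like T) to 331 (B) genes at an unadjusted p under 0.05, and DESeq2 called 3 genes in B-like, 2 in CD8 T-like and 0 in the other 5 classes. With the replicate number as a block, edgeR called 92 genes in regulatory T, 17 in CD8 T, 12 in CD4 T, 12 in innate-like T and 10 in B-like cells. It called 0 in neutrophils and classical monocytes, and the replicate numbers are not known to pair the libraries. Over the 10 classes the count was 13 by DESeq2, and 69 without Smc3-WT replicate 1, 1691 without Smc3-WT replicate 2, 35 without Smc3-cKO replicate 1 and 94 without Smc3-cKO replicate 2. NK-like cells had 0 calls without either Smc3-cKO library, with Plcb4 at a log2 change of 3.07 without replicate 1 and 3.13 without replicate 2 (adjusted p 0.999 and 1), and nonclassical monocyte-like cells had 0 without Smc3-cKO replicate 2, with Plcb4 at a log2 change of 4.66 (adjusted p 0.0861).

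**Figure D4:**
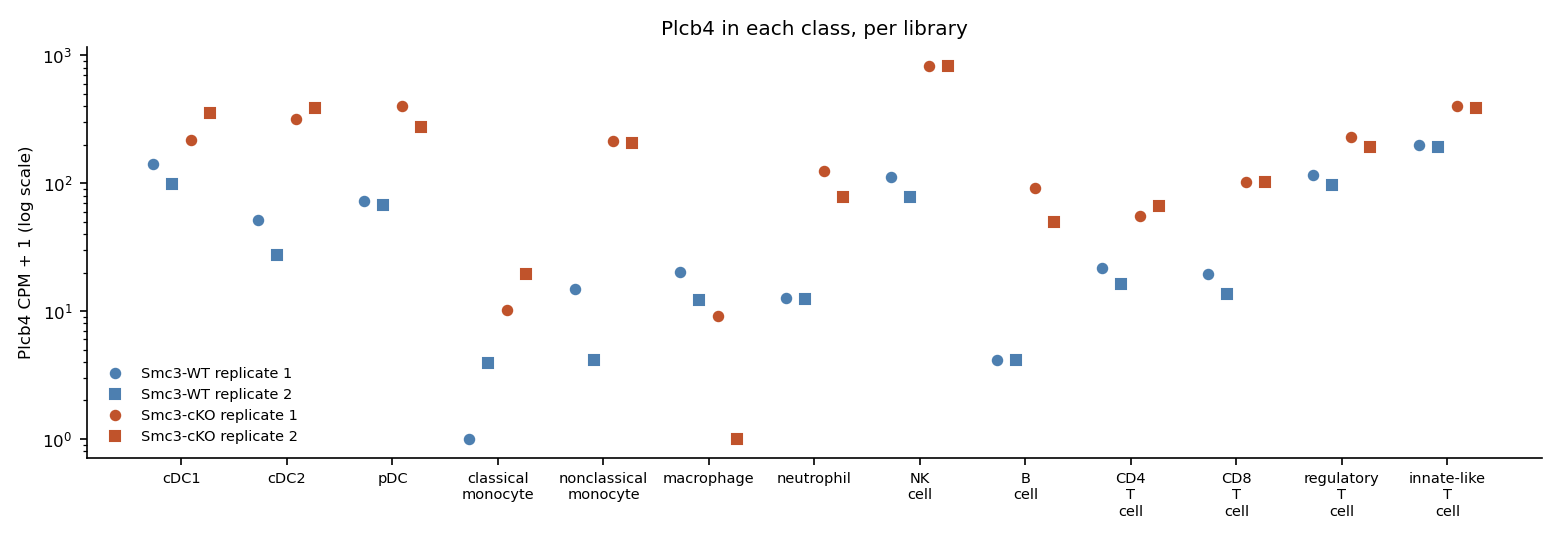
Plcb4 CPM + 1 (log axis) in the tested classes, with 1 point per library and CPM without TMM scaling. In 10 of 13 classes both Smc3-cKO libraries lie above both Smc3-WT libraries with a log2 ratio of at least 1.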

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

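No test in this part was chosen after its result was seen. In 2 comparisons the response to the genotype differed between cell types by a test of the difference itself, edgeR's interaction test with the library as a block. Between cDC1-like and cDC2-like cells 11 genes differed, among them Plcb4 and Cacnb2, higher in cDC2-like cells (2.06 and 2.36 on the log2 scale), and Stmn1, lower (-3.05). Plcb4 was higher in both Smc3-cKO libraries by a log2 ratio of at least 1 in 10 of 13 classes, so its rise is not particular to 1 subset. DESeq2 called 1 gene, and edgeR called 28 without Smc3-WT replicate 1, 174 without Smc3-WT replicate 2, 24 without Smc3-cKO replicate 1 and 1 without Smc3-cKO replicate 2. Between all cDC-like and pDC-like cells 63 genes differed, among them Siglech, with -2.64 in pDC-like relative to all cDC-like cells, Ccr2 and H2-Ab1. DESeq2 called 20 genes there, and edgeR called 29 without Smc3-WT replicate 1.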

How the results depend on the processing

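The tests with at most 20% mitochondrial UMIs, with doublets by rank and with clusters of 2 lineages kept were chosen after seeing the data. No direction of the 62 values of named genes turned under any alternative in which they were fitted. The number of calls depended on the processing, and except where the construction shows it the cause was not tested. Leaving out a library leaves 1 sample in a genotype, which edgeR assumes to vary like the others.

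In cDC1-like cells the 7 calls became 15 with DESeq2, 80 with no filter on low counts, 42 with the replicate block, 1 with equal numbers of cells, 4 with the stricter cell filters, 22 at Leiden resolution 2, 16 with 1 fit over all classes and 31 to 127 with a library left out. This class could not be tested with doublets kept, at most 20% mitochondrial UMIs or doublets by rank, where a library held too few of its cells. With doublets by rank, a cluster with Apol7c, Fscn1, Cxcl9 and Xcr1 among its leading genes was named mature cDC. It held 67 and 26 Smc3-WT and 56 and 10 Smc3-cKO cells, so the border between these 2 names depends on the setting. In cDC2-like cells the 63 calls became 291 with no filter, 23 with doublets kept, 33 with clusters of 2 lineages kept, 112 with 1 fit and 107 to 846 with a library left out. In all cDC-like cells the 37 calls became 129 with DESeq2, 476 with no filter, 273 with the replicate block, 10 with the stricter filters, 113 at Leiden resolution 2, 75 with at most 20% mitochondrial UMIs, 72 with doublets by rank, 177 with 1 fit and 63 to 253 with a library left out. In pDC-like cells the 0 calls of edgeR and of DESeq2 (171 genes at an unadjusted p under 0.05) became 14 with no filter, 3 with the block, 1 with 1 fit and 8 to 33 with a library left out. In the 10 other classes the 8 calls became 13 with DESeq2, 372 with no filter, 169 with the block, 15 with 1 fit and 35 to 1691 with a library left out. The replicate numbers of the 2 genotypes are not known to pair the libraries. The block removes a shared difference between replicates 1 and 2, whose correlation across genes was 0.163 in cDC2-like and 0.543 in B-like cells, where genes are not independent.

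The difference between cDC1-like and cDC2-like cells went from 11 genes to 59 with no filter, 1 with DESeq2 and 1 to 174 with a library left out, and that between all cDC-like and pDC-like cells from 63 to 20 with DESeq2 and 29 to 70 with a library left out. The 35 list calls in DC classes became 0 with an estimated correlation and 1 with fry, and the 98 in other classes 0 and 0. On simulated lists the estimated correlation also made 0 calls, so its 0 alone does not show that the lists were unchanged. The simulated genes were independent, so the simulation cannot show that the preset correlation of 0.01 holds for lists whose members move together. By edgeR 0 class shares passed in any setting (1 at an unadjusted p under 0.05 with the settings of the report), and the log2 change of the cDC2-like share, 0.10, became -0.39 relative to cells that are neither lymphoid nor erythroid, -0.04 with the stricter filters and -0.48 with clusters of 2 lineages kept. With a library left out it ranged from -0.22 to 0.52 (-0.14 without Smc3-cKO replicate 2), that of cDC1-like cells from -1.41 to 0.68 (0.01 without Smc3-WT replicate 1), of all cDC-like cells from -0.37 to 0.15, of pDC-like cells from -0.29 to 1.58, of classical monocyte-like cells from 1.09 to 2.38, of nonclassical monocyte-like cells from 0.77 to 2.29 and of macrophage-like cells from -2.73 to 0.02. Smc3 passed edgeR in 0 of 14 tests (0 at an unadjusted p under 0.05) and in 0 under each of 17 alternatives. Of the 62 named calls, 57 were kept with DESeq2, 62 with RLE factors and with no filter, 60 with the block, 56 to 62 with a library left out, 41 of 61 fitted with equal numbers of cells, 41 of 60 with the stricter filters, 40 of 55 with doublets kept and 57 of 62 when clustered without the called genes. Mature cDC-like cells could be tested only with doublets kept, 13 genes up and 25 down, and with at most 20% mitochondrial UMIs, 5 up and 1 down. The stricter filters left too few classical monocyte-like, innate-like T, macrophage-like and pDC-like cells for a test.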

Other observations

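The tests of the explanations below were chosen after the results were seen, except that of RNA from other cells for the genes that fell in cDC2-like cells. In cDC2-like cells genes of homing and DC subset differences also passed when adjusted over their lists alone. Of the chemokine receptor genes, Ccr2 and Ccr9, a gut homing receptor, had log2 changes of 1.40 (SE 0.34) and 1.35 (SE 0.35), and Ccr6 -2.03 (SE 0.57). Each of these 3 passed when adjusted over the list alone and 0 of them over all genes by edgeR, and camera gave an adjusted p of 0.0271 (adjusted p = 0.58 with an estimated correlation). Tbx21, the T-bet factor, went from 31.9 to 1.71 CPM, a log2 change of -3.63 (SE 0.78) that passed over the DC factor list alone and not over all genes (adjusted p 0.0641 by edgeR). Pola1, a DNA polymerase subunit, fell with a log2 change of -1.86 (SE 0.32, adjusted p 0.0251). Ribosomal protein and glycolysis genes were higher by camera (adjusted p 0.000221 and 0.0025; adjusted p = 0.834 and 0.58 with an estimated correlation), with medians of log2 change of 0.28 and 0.52. These medians were -0.32 and 0.14 without Smc3-WT replicate 1 and 1.41 and 1.05 without Smc3-WT replicate 2.

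Outside the DC classes, interferon-stimulated genes passed camera as higher in 7 of 10 classes, with medians of log2 change from 0.11 to 0.62 over the 10, and with an estimated correlation in 0. Without Smc3-cKO replicate 1 the median went from 0.62 to 0.21 in nonclassical monocyte-like, from 0.58 to -0.06 in classical monocyte-like and from 0.29 to -0.21 in B-like cells, while it was 0.27 and 0.31 in CD4 T-like cells. Interferon-gamma inducible GTPases passed as higher in 5 of 10 classes and immediate early genes in 5 of 10, MHC class II genes as lower in 8 of 10 and erythroid genes as lower in 6 of 9. With an estimated correlation 0 of these lists passed in any of the classes. Without Smc3-WT replicate 1 the median of the MHC class II genes went from -1.52 to -0.10 in CD4 T-like and from -1.14 to 0.45 in NK-like cells, where the B cell genes were also lower (medians -1.81 and -1.64, and -0.12 and -0.16 without that library). The median of the erythroid genes went from -1.53 to 1.57 in B-like cells without the same library. Haemoglobin made up 2.23% and 0.204% of UMIs in the Smc3-WT libraries and 1.16% and 0.0384% in the Smc3-cKO libraries. The red cell content thus differed by more between the replicates of a genotype than between genotypes.

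Genes at 2 loci were higher in both Smc3-cKO libraries in many classes, Plcb1, 9630028H03Rik and Plcb4 on chromosome 2 (134786164 to 136014602) and Itgad, 4931431B13Rik and Cox6a2 on chromosome 7 (128173933 to 128206366). A gene counted as higher in a class where both Smc3-cKO libraries lay above both Smc3-WT libraries with a log2 ratio of at least 1. RNA from myeloid cells in the other classes stays open for these genes as a set. In NK-like cells Plcb4 was at 828 and 820 CPM in Smc3-cKO, without TMM scaling. In no tested DC, monocyte, macrophage or neutrophil class did a library exceed 402 CPM. RNA from those classes alone thus cannot give the Plcb4 level of NK-like cells. The highest median log2 change of monocyte and macrophage genes was -0.87 over B, CD4 T, CD8 T, NK and regulatory T-like cells. In innate-like T cells the median over 5 genes was -0.015. Smc3-WT replicate 1 held 287 macrophage-like cells, against 88 in Smc3-WT replicate 2 and 79 and 29 in Smc3-cKO. A fall that follows that library could hide a rise, so these medians cannot decide. A local cause at the 2 loci, such as an inserted transgene built on Itgax, stays open: of 12 genes higher in at least 4 classes, 6 had another within 500 kb, against at most 4 in 10000 random sets, but the nearness of these genes prompted the test and so lends it no support. Itgad overlaps 4931431B13Rik and Cox6a2, whether they share reads was not tested, and Itgax, whose gene starts at 128129526 beside Itgad, was itself higher in 0 of 9 classes. Loss of Smc3 in the cells of these classes stays open, since Smc3 RNA was at -0.55 or above in every class tested and its tags may lie outside the deleted part.

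The 53 genes that fell in cDC2-like cells had a median log2 change of -2.79 while the Cd209a-led cluster held more of the class in Smc3-cKO, 61.3% against 17.9%, and the Adam23-led cluster less. These shares leave out an unnamed cluster led by Cd209a and Cyp7b1, with 45 and 105 Smc3-WT cells and 5 and 8 Smc3-cKO cells. That shift alone, with Smc3-WT levels in each cluster, gives values down to -1.09, a limit that holds for the clustering without the called genes only. In the clustering used for the tests, the Adam23-led cluster held 83.3% and 75.3% of cDC2-like cells in Smc3-WT and 21.0% and 26.9% in Smc3-cKO. The 53 genes were also chosen by their fall in the same cells. Their median therefore cannot decide whether the shift is the whole cause. RNA from other cells in the Smc3-WT libraries is argued against by a median level 46.1 times that in CD4 T-like cells. Within the Adam23-led cluster the median was -1.65, and 53 of 53 genes were lower. Within the Cd209a-led cluster it was -0.74 over the 30 genes above the floor, of which 22 were lower and 8 higher. How much of the fall comes from the shift and how much from changes within a cluster stays open. The same holds for the 10 genes that rose, with a median of 2.02 observed and 1.13 from the shift alone. Within the Adam23-led cluster 7 of them were higher and 3 lower, and within the Cd209a-led cluster 10 were higher. Siglech went from 21.8 to 15.9 CPM in the former and from 104 to 229 CPM in the latter. The shift alone gives it 0.98 against 2.10 observed.

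B cell genes were lower in Smc3-cKO in 8 of 10 other classes by camera and in 0 with an estimated correlation, and in CD4 T-like cells they summed to 2230 and 738 CPM in Smc3-WT against 775 and 624 CPM in Smc3-cKO, with a median log2 change of -1.81, and -0.12 without Smc3-WT replicate 1. Within each library the level differed between CD4 T, CD8 T and both monocyte classes by at most 1.55-fold. Free RNA from B cells there, most of it in Smc3-WT replicate 1, would give such even levels. Doublets left among the CD4 and CD8 T cells stay open. Removal by rank of the score left at least 92.7% of the level in that library, but it hardly changed these classes. There CD4 T-like cells went from 1405 to 1393 and CD8 T-like cells from 916 to 872, so the removal cannot decide. Free RNA as the only source in every class is argued against by levels that differed up to 18.6-fold within a library between the classes that are neither B cells nor DC. In Smc3-WT replicate 1 NK-like and innate-like T cells held 5050 and 7310 CPM, and the same removal left at most 46.7% of that, so doublets may be a source there. B-like cells were 49.6% and 61.3% of cells in Smc3-WT and 53.5% and 59.0% in Smc3-cKO (log2 change 0.02, adjusted p 0.982 by edgeR), and a difference in B cell death was not tested and stays open.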
